A study of Homo sapiens with 12 samples.

How the data were processed

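HDLM-2 cells, a human line established from Hodgkin lymphoma, were profiled on Illumina HumanHT-12 V3 bead arrays after 24 hours in 4 conditions: control, 100 nM givinostat, 5 µM sorafenib, or both drugs. Each condition had 3 arrays, named A, B and C, and 12 arrays were used in all. The labels do not say whether the 3 arrays of a condition came from separate cultures, so every p-value measures only the spread between arrays. With 3 arrays per group, the number of arrays limits the precision of every value.

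Biotin-labelled RNA was hybridised and read with BeadStudio per the labels, which give no version of it. The deposited non-normalized file holds, per array, a bead-averaged intensity for each of 48803 probes, from 69.7 to 72773, with no background subtraction. Beside each intensity the deposited file holds a fraction between 0 and 1 that its header calls a detection p-value. That fraction rose with intensity in every array (lowest Spearman correlation 0.992), so it was read as 1 minus the detection p-value. The authors' processed file holds linear intensity after quantile normalization between the 12 arrays: its sorted columns matched the mean of the sorted non-normalized signals within 0.217 units at the 99th percentile.

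The non-normalized intensities were background-corrected by the normal-exponential method of limma 3.58.1, with the background taken from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale (R 4.3.3, statmod 1.5.0, the data.table package, version 1.17.8). A probe entered when its detection p was under 0.05 on all 3 arrays of at least 1 group, which 16927 probes met. Gene symbols came from the supplied table of the platform's probes: 28098 probes had 1 symbol, 13 had several and 20692 had none there. Of the detected probes, 14039 had 1 symbol and 2888 did not and were left out. Where a gene had several probes, the one with the highest mean over the 12 arrays stood for it, which left 10529 genes.

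Group means were fitted with limma over all 12 arrays (8 residual and 4.04 prior degrees of freedom), and p-values from the moderated test were two-sided and adjusted by the Benjamini-Hochberg method over the 10529 genes. A gene counted as changed at an adjusted p under 0.05; a second count also asked for at least a 2-fold change. The 5 group comparisons were each drug and the combination against control, and the combination against each drug. The interaction tested whether the change with both drugs differed from the sum of the changes with each drug on the log2 scale, and a moderated F test asked for any difference among the 4 groups. Values are given as log2 changes with standard errors (SE) from this fit. For a gene above background on no array of a group, the fold was computed against the background limit and is given as "at least". A gene's arrays not overlapping between groups has a 10% chance in 3 against 3 when the gene was not chosen by a test.

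Each of 32 gene lists, fixed from textbook knowledge, was tested in the 6 contrasts with limma's camera at a preset correlation of 0.01, adjusted over the 192 tests; camera with an estimated correlation and fry were the alternatives. Lists are said to pass or to be called by camera at the preset correlation. Of 53 such calls fry kept 52, and it also called 45 of the 139 tests that camera did not. A list not called here may therefore pass with fry. But fry asks whether members changed at all, and camera whether they changed more than other genes. A call kept by fry is therefore no check of camera's call. With an estimated correlation 3 of 11 calls held for givinostat, 4 of 8 for sorafenib and 3 of 12 for the combination. Against givinostat 3 of 10 held, against sorafenib 3 of 11, and in the interaction 0 of 1. Members were also counted after adjustment over the list alone. A list needed 5 tested members. Lists share genes: 16 of 30 tested NF-kappaB targets, 12 of 26 Hodgkin Reed-Sternberg cell genes and 16 of 31 genes widely raised by histone deacetylase inhibitors were also in another list, as were 8 of 25 histone genes, 7 of 22 JAK-STAT targets and 5 of 8 members of the metallothionein list. That list holds 6 metallothionein genes tested beside SLC30A1 and MTF1, and its calls are not separate from those of the histone deacetylase inhibitor list. Relations between comparisons were correlations of log2 changes across genes, which are not independent replicates, set beside 200 simulations of unchanged groups that shared the same arrays.

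Genes were named by rule. For each contrast with control these were the 10 largest rises and 10 largest falls among changed genes whose arrays did not overlap with control, and for the other contrasts the 5 largest each way. Up to 4 members with the smallest p stood for each list. By this rule BCL2L11, CDKN1A, TNFRSF8, MKI67 and the drug target genes were named in every contrast, whether or not they passed. Not every value of a drug target gene that did not pass is given below. Probes with no symbol, several symbols or a placeholder symbol were left out. The comparisons, their gene and list tests, the lists and this naming rule were fixed before the data were examined. Tests and settings chosen or changed later are named as such where their values are given or in the last section. All list results without a single array belong to these.

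The alternatives were no background correction, the authors' quantile values, median scaling, cyclic loess, no detection filter, detection p under 0.01 on all 12 arrays, the mean of a gene's probes, a trended robust prior, array weights, fitting only the groups compared, the array letter as a block, and leaving out each array of the groups compared. A slide block was not run, since the files name no slides. Calls were tested on simulated data of this design: for givinostat against control, true log2 changes of 0.5 were called in 32.8% of genes, of 1 in 95.5% and of 2 in 100%, with 12 false calls among 164. For the interaction the shares were 10.4%, 64.2% and 97.0%, with 118 calls, and simulations with no change gave 0 calls. In the simulations with changes, 200 of 10529 genes changed, and the noise of each gene was drawn independently. The adjusted threshold is stricter where fewer genes change. The shares therefore do not give the power in the real data, where givinostat had 3509 calls and the interaction 2. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No genome coordinates were used here.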

Results

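Expression was measured on 12 bead arrays of HDLM-2 cells, 3 arrays for each of control, givinostat (a histone deacetylase inhibitor, 100 nM), sorafenib (an inhibitor of RAF and receptor tyrosine kinases, 5 µM) and their combination, all at 24 hours. Mean non-normalized intensity ran from 1034 units on sorafenib array C to 1629.7 on control array B, and from 16382 probes on sorafenib array C to 17934 on combination array A were above background. Sorafenib array C also stood apart in its mean correlation with its group (0.989, others up to 0.994) and its root mean square deviation from its group mean (0.221 log2 units, others 0.147 to 0.175). The first principal component held 55.7% of the variance and separated the arrays with givinostat from those without, and the second, with 11.5%, separated the arrays with sorafenib from those without. Of 10529 genes tested, 4902 differed among the 4 groups.

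**Figure D1:**
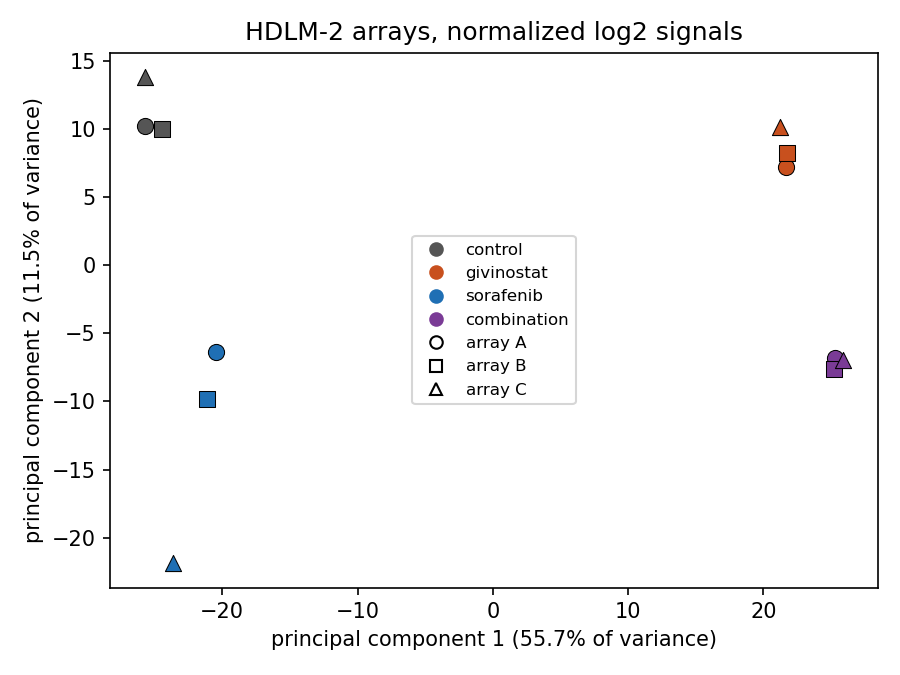
Position of each of the 12 arrays on the first 2 principal components of the normalized log2 signals, with colour for the group and marker shape for the array letter. Givinostat and combination arrays lie on the right along the first component (55.7% of the variance), and sorafenib array C lies lowest along the second (11.5%).

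Givinostat against control addressed what the histone deacetylase inhibitor did alone. SELENOP on chromosome 5, which encodes a plasma selenium carrier, was at least 12.4-fold higher (log2 change 4.12 ± 0.16 SE, n = 3 arrays per group, adjusted p = 1.78e-08) and was above background on 3 of 3 givinostat and 0 of 3 control arrays. CDKN1A, a cyclin-dependent kinase inhibitor gene, rose by 1.91 ± 0.13 on the log2 scale. IGLL1, a surrogate light chain gene of B cell precursors, fell by 3.01 ± 0.17, and NFKBIA, which encodes an inhibitor of NF-kappaB and is itself an NF-kappaB target, fell by 1.74 ± 0.14. TNFRSF8, which encodes the Hodgkin lymphoma marker CD30, fell by 1.15 ± 0.22 (adjusted p = 0.00191).

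The other largest rises with givinostat were in COXFA4L3 (3.28), SGSM1 (3.09) and the choline transporter-like gene SLC44A2 (2.98). They were joined by genes above background on 0 of 3 control arrays: AKR1C3, a steroid and prostaglandin reductase gene (at least 4.90-fold), ZNF365 (at least 5.46-fold), LINC03024 (at least 4.69-fold), ANKRD22 (at least 4.17-fold), ERICH3 (at least 4.21-fold) and ZNF467 (at least 4.54-fold). The other largest falls were in the agmatinase gene AGMAT (-2.50), GAS1 (-2.26), EMILIN1 (-1.96), NGEF (-1.93), KRTAP17-1 (-1.82), MOK (-1.81) and the NADPH oxidase gene NCF1 (-1.78). KCTD15 was above background on 0 of 3 givinostat arrays and was at least 2.65-fold lower.

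Genes of growth and DNA replication fell with givinostat. Of 34 MYC and ribosome biogenesis genes, 27 fell and 0 rose (31 fell when adjusted over the list alone; camera adjusted p = 7.47e-11, and 0.00926 with an estimated correlation). CAD (-0.93), RRP12 (-0.98), LYAR (-0.84) and PPAN (-0.92) were among them. Of 41 G1/S and DNA replication genes, 30 fell and 1 rose (31 and 1 adjusted over the list alone; adjusted p = 9.19e-10, and 0.0113 with an estimated correlation). UHRF1 (-1.02), CDC45 (-0.81), PCNA (-0.91) and MCM7 (-0.70) had the smallest p. Of 27 proteasome genes, 12 fell and 0 rose (13 fell adjusted over the list alone; adjusted p = 3.58e-04, but adjusted p = 0.178 with an estimated correlation). PSMA1 (-0.40) and PSMB5 (-0.63) were among those. Of the 6 cyclin-dependent kinase inhibitor genes tested, 4 rose and 0 fell, both over all genes and adjusted over the list alone (adjusted p = 0.0217, but adjusted p = 0.102 with an estimated correlation). They were CDKN1A, CDKN2B (1.05), CDKN2D (0.63) and CDKN3 (0.66). The call of CDKN3 was lost under median scaling (adjusted p = 0.0684).

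NF-kappaB targets, whose pathway is constitutively active in many Hodgkin lines, fell as a list with givinostat: 19 of 30 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 4.86e-07, and 0.0102 with an estimated correlation). RELB (-1.44), LTA (-1.56) and NFKBIA fell, and the chemokine gene CXCL10 rose by 1.87. Of 22 JAK-STAT targets, 13 fell and 2 rose (13 and 3 adjusted over the list alone; adjusted p = 0.00174, but adjusted p = 0.0801 with an estimated correlation). BCL6 (-1.11), STAT5A (-1.07), CISH (-0.90) and STAT6 (-0.79) fell. Of 26 Hodgkin Reed-Sternberg cell genes, 13 fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 0.0149, but adjusted p = 0.163 with an estimated correlation). IL6 (-1.25) and TNFRSF9 (-0.88) fell, and ID2 (0.64) rose, a call lost without givinostat array B (adjusted p = 0.0556).

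Other lists rose with givinostat at the preset correlation. Of 31 genes widely raised by histone deacetylase inhibitors, 14 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 3.67e-04, but adjusted p = 0.0801 with an estimated correlation). CRIP2 (at least 3.51-fold), MT2A (0.89) and DPYSL3 (0.92) rose beside CDKN1A. Of 30 autophagy and lysosome genes, 15 rose and 0 fell (17 and 2 adjusted over the list alone; adjusted p = 6.8e-04, but adjusted p = 0.0671 with an estimated correlation). The ATG8-family gene GABARAPL1 rose by 2.78, MAP1LC3A by 1.24, WIPI1 by 0.82 and MAP1LC3B by 0.68. Of 8 genes of metallothioneins and zinc handling, 6 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.00166, but adjusted p = 0.178 with an estimated correlation). MT1X (1.16), MT1G (0.78) and the zinc exporter gene SLC30A1 (0.69) rose, though 5 of the 8 are also in another list and MT1 probes can read several near-identical transcripts. Of 5 erythroid marker genes, HBD rose (at least 4.98-fold) and 0 fell (4 rose adjusted over the list alone; adjusted p = 0.018, but adjusted p = 0.0942 with an estimated correlation). On genes detected on all 12 arrays, a filter that left out HBD, this list was not called (adjusted p = 0.672). HBG1 and HBG2 (adjusted p = 0.0533 and 0.0714), near-identical in sequence, did not pass over all genes, and with HBD at its bound the list median was 0.59.

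In all, 3509 genes (33.3%) changed with givinostat, 1856 higher and 1653 lower, and 456 changed at least 2-fold, 341 higher and 115 lower. Of the 3509, 3421 had no overlap between the 3 and 3 arrays; the chance of 10% holds for genes not chosen by a test, so this count is no separate evidence. Median scaling put the median of all genes at -0.12 and the split at 1106 higher and 1996 lower, and without background correction 135 genes changed at least 2-fold, since log2 changes shrink when background is left in. Of 2759 genes with several detected probes, 11 had probes called in opposite directions, none of which is named here. In 795 of the 2759, some probes were called and others were not when each probe was fitted singly.

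Sorafenib against control addressed the kinase inhibitor alone, and the amino acid stress list had the smallest p of the 32 lists. ASNS, the asparagine synthetase gene, rose by 0.98 ± 0.09 (SE, n = 3 arrays per group, adjusted p = 4.1e-04), and the serine synthesis gene PSAT1 was 2.14-fold higher. The cysteine synthesis gene CTH rose by 1.07 ± 0.11 and the lipoprotein receptor gene VLDLR by 1.05 ± 0.10. The linker histone gene H1-2 fell by 1.30 ± 0.12 and H2AJ fell by 1.29 ± 0.13. The keratin-associated protein gene KRTAP9-3 fell by 2.15 ± 0.24, KRTAP9-4 fell by 1.63 ± 0.19 and KRTAP9-8 was at least 2.54-fold lower. Their sequences are near-identical, so which of them changed is uncertain.

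The other largest rises with sorafenib were in ASS1, the argininosuccinate synthase gene (1.54), CYP4Z1 (1.37), TNFRSF21 (1.23), SERPINI1 (1.23), COLQ (1.21), B3GALT4 (1.21), TWF2-DT (2.30-fold), INHBE (1.19), C4BPB (1.17) and MAP2K6 (at least 1.35-fold). The other largest falls were in MIR503HG (-1.67), FOS (-1.24), FTSJ3 (-1.13), NDUFB4 (-1.08) and KRTAP1-5 (at least 1.41-fold). When only the compared groups were fitted, ASS1 and SERPINI1 (adjusted p = 0.0668 and 0.0574), B3GALT4 (0.0828), FTSJ3 (0.117) and NDUFB4 (0.0668) were not called. With no detection filter and with array weights, B3GALT4 (adjusted p = 0.0554 and 0.0621) and FTSJ3 (0.0654 and 0.0753) were not called. The call of B3GALT4 was lost without control B or C or sorafenib A or C (adjusted p up to 0.0979), and that of MAP2K6 without control A or B or sorafenib B or C (up to 0.0758). FTSJ3 was lost without any array but sorafenib B (up to 0.108). NDUFB4 was lost with the mean of its probes (-0.51), without sorafenib B, and without control B, where its sign turned (0.07, adjusted p = 0.86). The probe that stood for a gene was chosen anew with each array left out, so that value may belong to another NDUFB4 probe.

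Of 32 amino acid and integrated stress response genes, 13 rose with sorafenib and 0 fell (21 rose adjusted over the list alone; camera adjusted p = 2.04e-12, and 0.00229 with an estimated correlation). Of 25 histone genes, 9 fell and 0 rose (13 fell adjusted over the list alone; adjusted p = 5.08e-10, and 0.0162 with an estimated correlation). H3C10 (-0.79) and H2AC18 (-0.70) fell beside H1-2 and H2AJ, though histone probes can read related copies. Of 34 MYC and ribosome biogenesis genes, 4 fell and 0 rose (8 fell adjusted over the list alone; adjusted p = 1.25e-08, and 0.0102 with an estimated correlation). They were PA2G4 (-0.56), NOP16 (-0.63), NOLC1 (-0.43) and PPAN (-0.46). The heat shock list was lower (adjusted p = 4.06e-04, and 0.0309 with an estimated correlation; median -0.21) although 0 of its 17 members passed, over all genes or adjusted over the list alone. CHORDC1 stood at -0.42 and BAG3 at -0.34. The call of NOLC1 was lost without any array but sorafenib C (adjusted p up to 0.112) and that of PPAN without any but sorafenib A (up to 0.153), and both with no detection filter. When only the compared groups were fitted, H3C10, H2AC18, PA2G4 and NOP16 were not called (adjusted p = 0.0555, 0.0594, 0.0598 and 0.0682), nor were NOLC1 and PPAN. PPAN was also lost with the array letter as a block.

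Of 18 ERK pathway targets, 6 fell with sorafenib and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00611, but adjusted p = 0.0671 with an estimated correlation). The immediate early genes FOS and EGR1 (-0.88 ± 0.20, adjusted p = 0.032) and MAFF (-0.84) fell, and JUN rose by 0.64. EGR1 and FOS were each above background on 1 of 3 sorafenib arrays. On genes detected on all 12 arrays, a filter that left both out, the list was not called (adjusted p = 0.668). Each of these calls was lost without 4 of the 6 arrays. EGR1 was lost without control A or B or sorafenib B or C (adjusted p up to 0.102), and FOS without control A or C or sorafenib A or C (up to 0.0846). MAFF was lost without control A or C or sorafenib B or C (up to 0.0915), and JUN without control A or B or sorafenib A or B (up to 0.0758). EGR1, MAFF and JUN were not called when only the compared groups were fitted, nor were EGR1 and MAFF with no detection filter, EGR1 without background correction (0.0555), MAFF with the mean of its probes or JUN under median scaling (0.14).

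Of 27 proteasome genes, PSMD8 (-0.49) and PSMD2 (-0.49) fell with sorafenib and 0 rose (4 fell adjusted over the list alone; adjusted p = 1.74e-06, but adjusted p = 0.0916 with an estimated correlation). Of 41 G1/S and DNA replication genes, RRM2 (-0.68) fell and 0 rose, also when adjusted over the list alone (adjusted p = 8.6e-04, but adjusted p = 0.0801 with an estimated correlation). Of 37 interferon response genes, 6 rose and 0 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0279, but adjusted p = 0.114 with an estimated correlation). IFIT3 (0.62), ISG20 (0.47), OAS3 (0.64) and RIGI (0.52) rose. The list median of 0.12 turned to -0.05 under median scaling, where the median of all genes was -0.17. This list was lost without sorafenib B (adjusted p = 0.0622). So were IFIT3 (also without control B or C), ISG20 (also without control A or C), OAS3 (also without control C) and RIGI (also without control B or C), with adjusted p up to 0.0685, and all 4 under median scaling (up to 0.248). PSMD8 was lost without any array but sorafenib A, PSMD2 without any but control B, and RRM2 without control A or C or sorafenib B or C (adjusted p up to 0.113, 0.145 and 0.0917). None of these 7 genes was called when only the compared groups were fitted, nor were PSMD8, PSMD2 and RRM2 with no detection filter or PSMD2 with the array letter as a block.

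In all, 482 genes (4.58%) changed with sorafenib, 315 higher and 167 lower, and 28 changed at least 2-fold, 17 higher and 11 lower. Without background correction, 3 changed at least 2-fold, and 10 did on genes detected on all 12 arrays. The count fell to 166 without sorafenib array B, 170 without control C, 221 without control A, 245 without control B and 251 without sorafenib C, and to 75 when only the compared groups were fitted. Median scaling gave 79 higher and 366 lower. All 482 genes had no overlap between the 3 and 3 arrays. Of 2759 genes with several probes, 0 had probes called in opposite directions, and 153 had some called and others not.

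The combination against control asked what both drugs did together. SELENOP was at least 15.1-fold higher (log2 change 4.41 ± 0.16 SE, n = 3 arrays per group, adjusted p = 1.58e-08), CRIP2 at least 5.13-fold and the delta globin gene HBD at least 5.78-fold. CDKN1A rose by 1.64 ± 0.13, VLDLR rose by 1.71 ± 0.10 and ASNS by 1.03 ± 0.09. IGLL1 fell by 3.09 ± 0.17, TNFRSF8 fell by 1.41 ± 0.22, and the ribonucleotide reductase gene RRM2 fell by 1.59 ± 0.15. EGR1 was at 0.21 ± 0.20 (adjusted p = 0.42) and FOS at -0.60 ± 0.27 (adjusted p = 0.0917), neither past the threshold.

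The other largest rises with the combination were in ZNF365 (at least 6.53-fold), LINC03024 (at least 6.14-fold), ANKRD22 (at least 5.36-fold), SGSM1 (3.09), COXFA4L3 (2.94), SLC44A2 (2.87) and CHI3L2 (2.86). The other largest falls were in AGMAT (-2.35), KRTAP9-4 (-2.35), GAS1 (-2.33), KRTAP9-3 (-2.22), MOK (-2.15), KRTAP17-1 (-1.86), CYB5D1 (-1.83), EMILIN1 (-1.79) and PRKAR1B (at least 2.98-fold lower).

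With the combination, 31 of 34 MYC and ribosome biogenesis genes fell and 0 rose (32 fell adjusted over the list alone; adjusted p = 3.16e-14, and 0.00452 with an estimated correlation). NOP16 (-1.23), RRP9 (-1.55), PPAN (-1.28) and RRP12 (-1.27) were lower. Of 41 G1/S and DNA replication genes, 31 fell and 0 rose (32 fell adjusted over the list alone; adjusted p = 2.94e-10, and 0.0102 with an estimated correlation). UHRF1 (-1.28), CDC45 (-0.96) and MCM5 (-1.09) were lower. Of 27 proteasome genes, 26 fell and 0 rose, also when adjusted over the list alone (adjusted p = 2.72e-08, but adjusted p = 0.0671 with an estimated correlation). PSMC6 (-0.53), PSMA1 (-0.50), PSMA6 (-0.54) and PSMB6 (-0.70) had the smallest p. Of 17 heat shock genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0237, but adjusted p = 0.0932 with an estimated correlation). DNAJA1 (-0.69), HSPH1 (-0.58), HSPA8 (-0.64) and HSP90AB1 (-0.65) fell.

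Of 30 NF-kappaB targets, 17 fell with the combination and 4 rose (18 and 4 adjusted over the list alone; adjusted p = 7.05e-04, and 0.0446 with an estimated correlation). RELB (-1.15), STAT5A (-1.20) and LTA (-1.20) fell and CXCL10 rose by 1.67. Of 22 JAK-STAT targets, 13 fell and 2 rose (15 and 2 adjusted over the list alone; adjusted p = 0.00262, but adjusted p = 0.0885 with an estimated correlation). BCL6 (-0.92), IL2RA (-0.69) and STAT6 (-0.65) fell. Of 32 integrated stress response genes, 12 rose and 2 fell (14 and 3 adjusted over the list alone; adjusted p = 0.00882, but adjusted p = 0.0671 with an estimated correlation). CTH (2.29-fold) and PSAT1 (1.48-fold) rose beside ASNS and VLDLR. Under median scaling this list was not called (adjusted p = 0.0755). The autophagy and lysosome list (12 of 30 rose, 1 fell, also adjusted over the list alone; adjusted p = 0.00438, but adjusted p = 0.0913 with an estimated correlation) again held GABARAPL1 (2.79) and MAP1LC3A (1.33).

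Of 31 genes widely raised by histone deacetylase inhibitors, 17 rose with the combination and 6 fell (18 and 8 adjusted over the list alone; adjusted p = 0.0134, but adjusted p = 0.178 with an estimated correlation). The actin regulator gene GSN (at least 2.44-fold) and DPYSL3 (1.12) rose. Of 6 cyclin-dependent kinase inhibitor genes, 4 rose and 0 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0193, but adjusted p = 0.095 with an estimated correlation). They were CDKN1A, CDKN2B (1.41), CDKN2D (1.01) and CDKN3 (0.62), the last not under median scaling (adjusted p = 0.111). Of 8 genes of metallothioneins and zinc handling, 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.018, but adjusted p = 0.301 with an estimated correlation), with MT2A (0.74) and MT1X (0.89). Of 5 erythroid genes, 4 rose and 0 fell (5 adjusted over the list alone; adjusted p = 0.00542, but adjusted p = 0.0723 with an estimated correlation). They were HBD, HBE1 (1.12) and the near-identical HBG1 (0.97) and HBG2 (at least 1.74-fold). On genes detected on all 12 arrays, a filter that left out HBD, the list was not called (adjusted p = 0.648).

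In all, 4356 genes (41.4%) changed with the combination, 2201 higher and 2155 lower, and 636 changed at least 2-fold, 446 higher and 190 lower. Without background correction, 205 changed at least 2-fold. Median scaling gave 1503 higher and 2287 lower. Of the 4356, 4252 had no overlap between the 3 and 3 arrays, and of 2759 genes with several probes 20 had probes called in opposite directions. In 856 of the 2759, some probes were called and others were not.

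**Figure D2:**
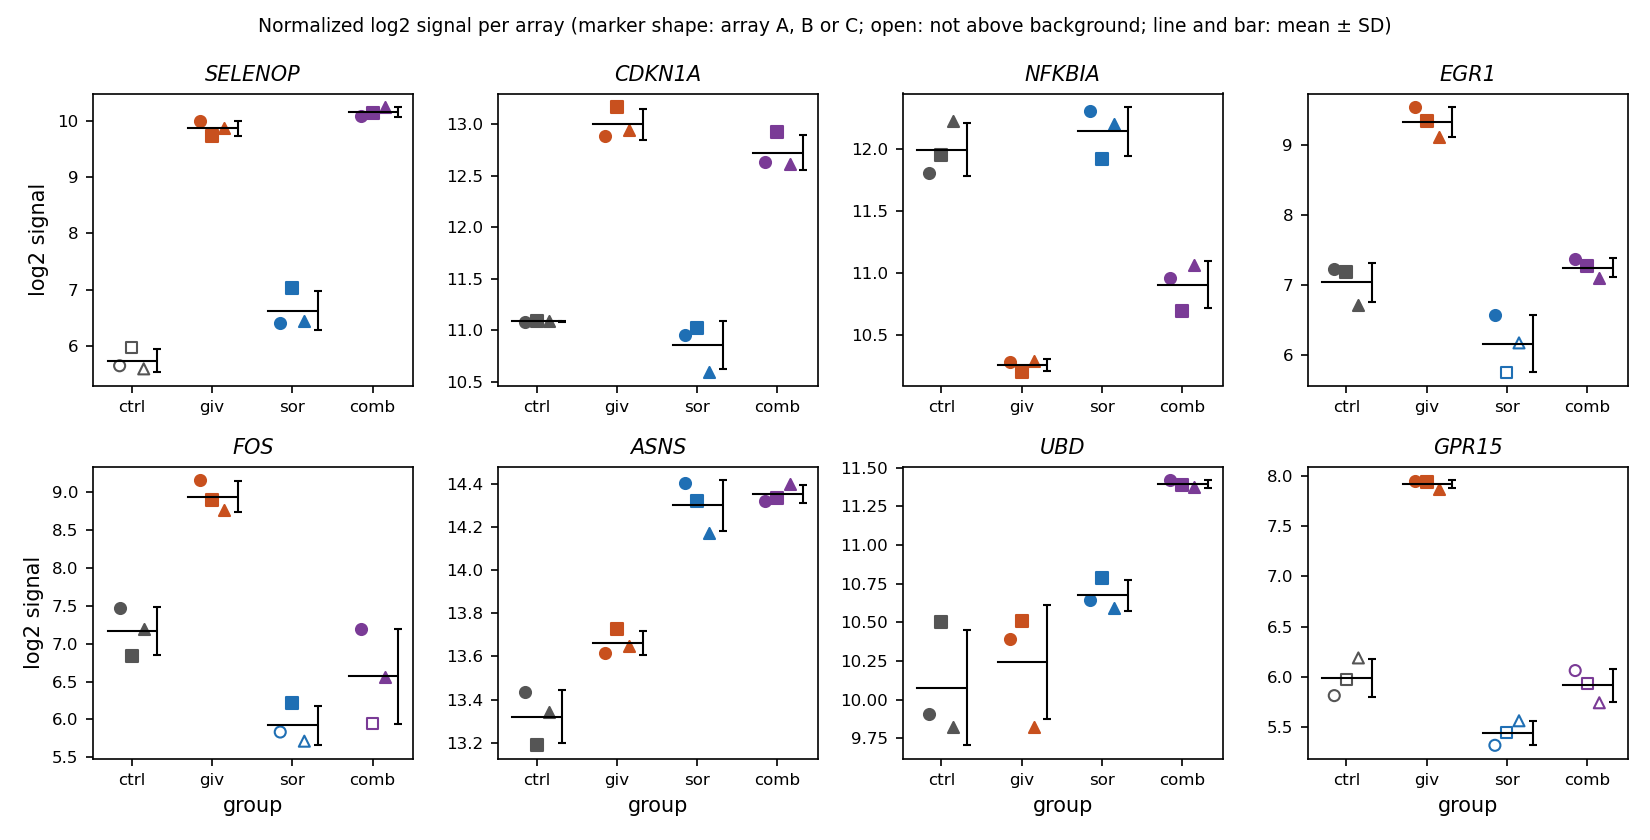
Normalized log2 signal of 8 genes on each array, by group (ctrl, control; giv, givinostat; sor, sorafenib; comb, combination). Points are arrays, open where not above background, lines are group means and bars are standard deviations (n = 3). EGR1 averaged 7.04 in control, 9.34 with givinostat, 6.16 with sorafenib and 7.25 with the combination, and GPR15 was above background on givinostat arrays alone.

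The combination against givinostat asked what sorafenib added to givinostat. EGR1 was 4.26-fold lower in the combination than with givinostat (log2 change -2.09 ± 0.20 SE, n = 3 arrays per group, adjusted p = 5.35e-04) and FOS was 5.17-fold lower (-2.37 ± 0.27, adjusted p = 0.0016). Both had risen with givinostat alone, EGR1 by 2.30 and FOS by 1.77. The chemoattractant receptor gene GPR15, above background on 3 of 3 givinostat arrays and 0 of 3 combination arrays, was at least 3.44-fold lower. The amino acid stress genes PSAT1 (0.76), CTH (0.85), VLDLR (0.76) and ASNS (0.69) were higher in the combination.

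The other largest differences between combination and givinostat were higher values of the ubiquitin-like gene UBD (1.15), C4BPB (1.13), ATXN7L1 (at least 1.67-fold), SPINK13 (1.08) and MTAP (1.08), and lower values of KRTAP9-4 (-1.96) and KRTAP9-3 (-1.74), near-identical genes. The call of UBD was lost without any 1 of the 3 combination arrays (adjusted p up to 0.0668), that of ATXN7L1 without givinostat A or combination A or B (up to 0.0816). That of MTAP was lost without givinostat A or C or combination A or B (up to 0.11), with no detection filter (0.052) and when only the compared groups were fitted (0.0772).

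Of 32 integrated stress response genes, 8 were higher in the combination than with givinostat and 0 lower (21 and 1 adjusted over the list alone; adjusted p = 1.09e-17, and 0.00114 with an estimated correlation). Of 25 histone genes, 7 were lower and 0 higher (11 lower adjusted over the list alone; adjusted p = 2.44e-07, and 0.0344 with an estimated correlation). H3C10 (-1.07), H4C8 (-0.80), H2AC18 (-0.70) and H2AC6 (-0.61) were among them. Of 34 MYC and ribosome biogenesis genes, RRP9 (-0.92) and NOP16 (-0.51) were lower and 0 higher (13 lower adjusted over the list alone; adjusted p = 3.73e-09, and 0.0102 with an estimated correlation). The call of RRP9 was lost without givinostat A (adjusted p = 0.0513) and that of NOP16 without any 1 of the 6 arrays (up to 0.109). H4C8 was lost without givinostat A or combination B (up to 0.0597), H2AC18 without givinostat A or C or combination A or C (up to 0.084), and H2AC6 without any array but combination C (up to 0.0997). Under median scaling NOP16 (0.178), H4C8 (0.0532), H2AC18 (0.0638) and H2AC6 (0.065) were not called, nor NOP16 with no detection filter (0.0612) or H2AC6 when only the compared groups were fitted (0.0598).

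Of 30 NF-kappaB targets, NFKBIA (0.65) was higher and 0 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00149, but adjusted p = 0.0572 with an estimated correlation). Of 26 Hodgkin Reed-Sternberg cell genes, TNFRSF9 (0.65) was higher and 0 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00186, but adjusted p = 0.0913 with an estimated correlation). Of 6 monocyte and macrophage markers, ITGAX (0.54) was higher (2 adjusted over the list alone; adjusted p = 0.0037, but adjusted p = 0.0671 with an estimated correlation). Of 18 ERK targets, EGR1 and FOS were lower and JUN (0.63) higher (5 and 1 adjusted over the list alone; adjusted p = 0.0193, but adjusted p = 0.0885 with an estimated correlation). This list was lost with the mean of a gene's probes (adjusted p = 0.123) and, on genes detected on all 12 arrays, its direction turned (adjusted p = 0.783). That filter left out EGR1 and FOS, so the turn does not bear on their falls. The proteasome list was lower (0 of 27 members past, 2 lower adjusted over the list alone; adjusted p = 2.45e-07, but adjusted p = 0.0801 with an estimated correlation). So was the G1/S list, where RRM2 (-0.80) passed, also adjusted over the list alone (adjusted p = 0.0149, but adjusted p = 0.163 with an estimated correlation). The endoplasmic reticulum chaperone list was lower (0 of 18 past, 3 lower adjusted over the list alone; adjusted p = 0.0207, but adjusted p = 0.121 with an estimated correlation), but not without combination A (adjusted p = 0.0727) or on genes detected on all 12 arrays (0.16).

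Of these genes, the calls of NFKBIA, ITGAX and JUN were lost without any 1 of the 6 arrays (adjusted p up to 0.138, 0.119 and 0.135). TNFRSF9 was lost without any array but givinostat B (up to 0.109), and RRM2 without givinostat A or C or combination A or C (up to 0.0977). None of NFKBIA, ITGAX, JUN and TNFRSF9 was called with no detection filter, and under median scaling ITGAX, JUN and TNFRSF9 were not called (0.0766, 0.148 and 0.0532). JUN was also lost when only the compared groups were fitted (0.0554) and with the array letter as a block (0.0642), NFKBIA when only the compared groups were fitted, and ITGAX with the mean of its probes (0.142).

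In all, 141 genes (1.34%) differed between combination and givinostat, 89 higher and 52 lower, and 15 differed at least 2-fold, 5 higher and 10 lower. Without background correction, 4 differed at least 2-fold, and 5 did on genes detected on all 12 arrays. All 141 had no overlap between the 3 and 3 arrays. The count was 32, 71 and 52 without givinostat A, B and C and 59, 39 and 46 without combination A, B and C, and 319 without background correction. Without sorafenib array C, a setting chosen after seeing the data, it was 224, and under median scaling it was 72 higher and 16 lower. Of 2759 genes with several probes, 0 had probes called in opposite directions, and 51 had some called and others not.

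Sorafenib's changes alone and on top of givinostat use no array in common. Across 10529 genes their log2 changes correlated at 0.355 (Spearman 0.312), against -0.0007 in simulations of unchanged groups. Of genes changed in both, 40 were higher (2.66 for independent calls), 22 lower (0.825 for independent calls) and 0 opposite. Givinostat and sorafenib changes, which share the 3 control arrays, correlated at 0.289 (Spearman 0.330), where unchanged groups sharing controls gave 0.473 to 0.537. Their covariance was 0.0362 against 0.0114 simulated, and 159 genes were higher in both (55.5 independent), 67 lower in both (26.2) and 67 opposite. Givinostat and combination changes correlated at 0.896 (unchanged groups 0.477 to 0.526; covariance 0.226 against 0.0115), with 1570 genes higher in both (388 independent), 1311 lower in both (338) and 6 opposite. Sorafenib and combination changes correlated at 0.418, where unchanged groups sharing controls gave 0.475 to 0.529 (covariance 0.0581 against 0.0114), with 212 higher in both (65.8 independent), 100 lower in both (34.2) and 33 opposite. In simulated pairs that share controls, those arrays were the only source of correlation, which fixed it near 0.5. A real correlation under that range therefore does not show that changes were less alike than in unchanged groups. The covariances, higher than simulated, are the fairer comparison. The simulations drew the noise of each gene independently, so their ranges may be narrower than for arrays whose genes deviate together. The simulated covariances include the shared controls and the independent counts do not. With 3 controls, each side of a division cannot keep 2, so part of the excess of these overlap counts may come from the shared controls.

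**Figure D3:**
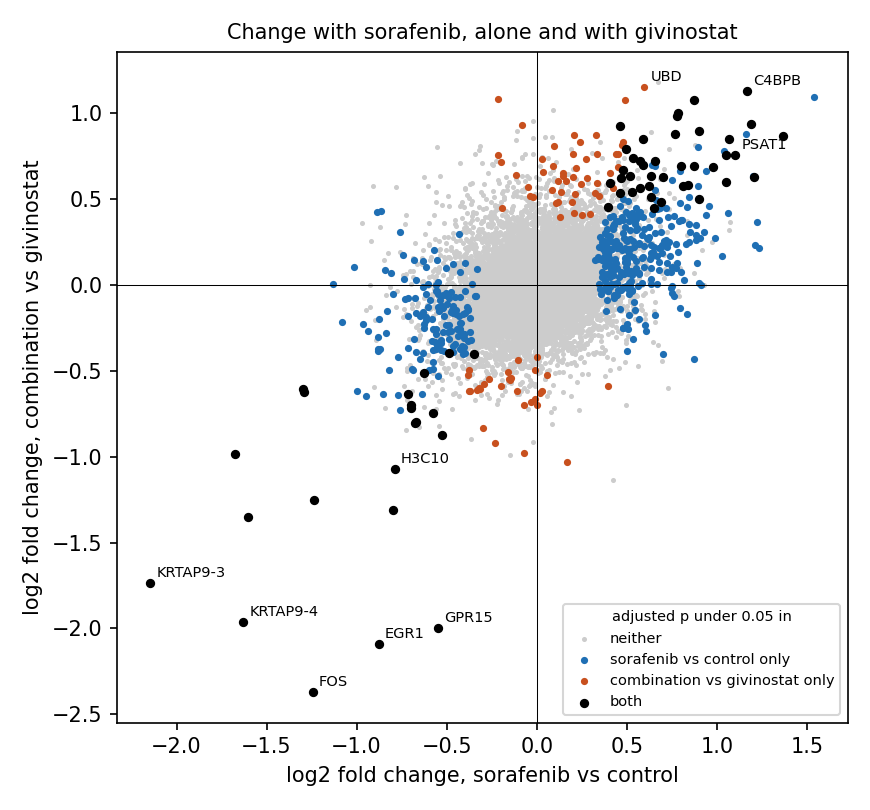
Log2 change of each of 10529 genes with sorafenib against control (horizontal) and in the combination against givinostat (vertical), coloured by which comparison had an adjusted p under 0.05. Of genes past both, 40 lie at upper right and 22 at lower left. GPR15 was above background only on givinostat arrays, so its horizontal value is a difference between background signals.

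The combination against sorafenib asked what givinostat added to sorafenib. SELENOP rose by 3.53 ± 0.16 (SE, n = 3 arrays per group, adjusted p = 8.25e-08), and CDKN1A by 1.87 ± 0.13. BCL2L11, which encodes the cell death protein BIM, was 1.91-fold higher in the combination than with sorafenib (0.93 ± 0.21, adjusted p = 0.00539). It was above background on 2 of 3 sorafenib arrays. Against control it did not pass with sorafenib (-0.66, adjusted p = 0.0996) or with the combination (0.27, adjusted p = 0.335). IGLL1 fell by 2.35 ± 0.17 and TNFRSF8 fell by 1.03 ± 0.22 (adjusted p = 0.00363). The other largest rises were in SLC44A2 (3.34), ANKRD22 (at least 5.37-fold), COXFA4L3 (3.17) and LINC03024 (at least 6.15-fold), and the other largest falls in AGMAT (-2.22), FAM20C (-2.14), CCDC121 (-1.90) and GAS1 (-1.89).

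Of 34 MYC and ribosome biogenesis genes, 25 were lower in the combination than with sorafenib and 0 higher (28 lower adjusted over the list alone; adjusted p = 5.08e-10, and 0.0102 with an estimated correlation). RRP9 (-1.32) was among them. Of 41 G1/S genes, 25 were lower and 0 higher (27 lower adjusted over the list alone; adjusted p = 7.19e-08, and 0.0201 with an estimated correlation). UHRF1 (-1.13) and MCM5 (-1.02) were among them. Of 30 NF-kappaB targets, 17 were lower and 2 higher (19 and 2 adjusted over the list alone; adjusted p = 3.97e-05, and 0.0201 with an estimated correlation). RELB (-1.41) and LTA (-1.48) were lower and CXCL10 (2.54) higher. Of 22 JAK-STAT targets, 12 were lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 7.05e-04, but adjusted p = 0.0671 with an estimated correlation). STAT5A (-1.37) and BCL6 (-1.07) were lower. Of 27 proteasome genes, 11 were lower and 0 higher, also adjusted over the list alone (adjusted p = 5.4e-04, but adjusted p = 0.184 with an estimated correlation). PSMC6 (-0.40) and PSMB6 (-0.50) were lower.

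Of 31 genes widely raised by histone deacetylase inhibitors, 17 were higher in the combination than with sorafenib and 2 lower, also adjusted over the list alone (adjusted p = 6.09e-04, but adjusted p = 0.0885 with an estimated correlation). CRIP2 (at least 5.14-fold), GSN (at least 2.44-fold) and TXNIP (1.59) were higher. Of 30 autophagy and lysosome genes, 12 were higher and 0 lower, also adjusted over the list alone (adjusted p = 8.5e-04, but adjusted p = 0.0671 with an estimated correlation), led by GABARAPL1 (2.55). Of 6 cyclin-dependent kinase inhibitor genes, 5 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00186, but adjusted p = 0.0647 with an estimated correlation). CDKN2B (1.28) was among them, beside CDKN1A. Of 5 erythroid genes, 4 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00242, but adjusted p = 0.0671 with an estimated correlation). HBD (2.73) was among them. On genes detected on all 12 arrays, a filter that left out HBD, the list was not called (adjusted p = 0.758). Of 25 histone genes, 8 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0193, but adjusted p = 0.215 with an estimated correlation). H2BC9 (0.98) and H1-2 (1.03) were among them. The list was not called without sorafenib B (adjusted p = 0.0622) or on genes detected on all 12 arrays (adjusted p = 0.137). Of 26 Hodgkin Reed-Sternberg cell genes, 11 were lower and 3 higher (12 and 3 adjusted over the list alone; adjusted p = 0.0415, but adjusted p = 0.223 with an estimated correlation). TRAF1 (-0.72) and IL2RA (-0.55) were lower. This list was lost without sorafenib A (0.0761), combination A (0.052) or combination B (0.0637), on genes detected on all 12 arrays (0.105) and with the mean of a gene's probes (0.0597).

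In all, 3720 genes (35.3%) differed between combination and sorafenib, 1873 higher and 1847 lower, and 466 differed at least 2-fold, 325 higher and 141 lower. Without background correction, 124 differed at least 2-fold. Median scaling gave 1951 higher and 912 lower. Of the 3720, 3601 had no overlap between the 3 and 3 arrays, and 22 of 2759 genes with several probes had probes called in opposite directions. In 906 of the 2759, some probes were called and others were not.

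**Figure D4:**
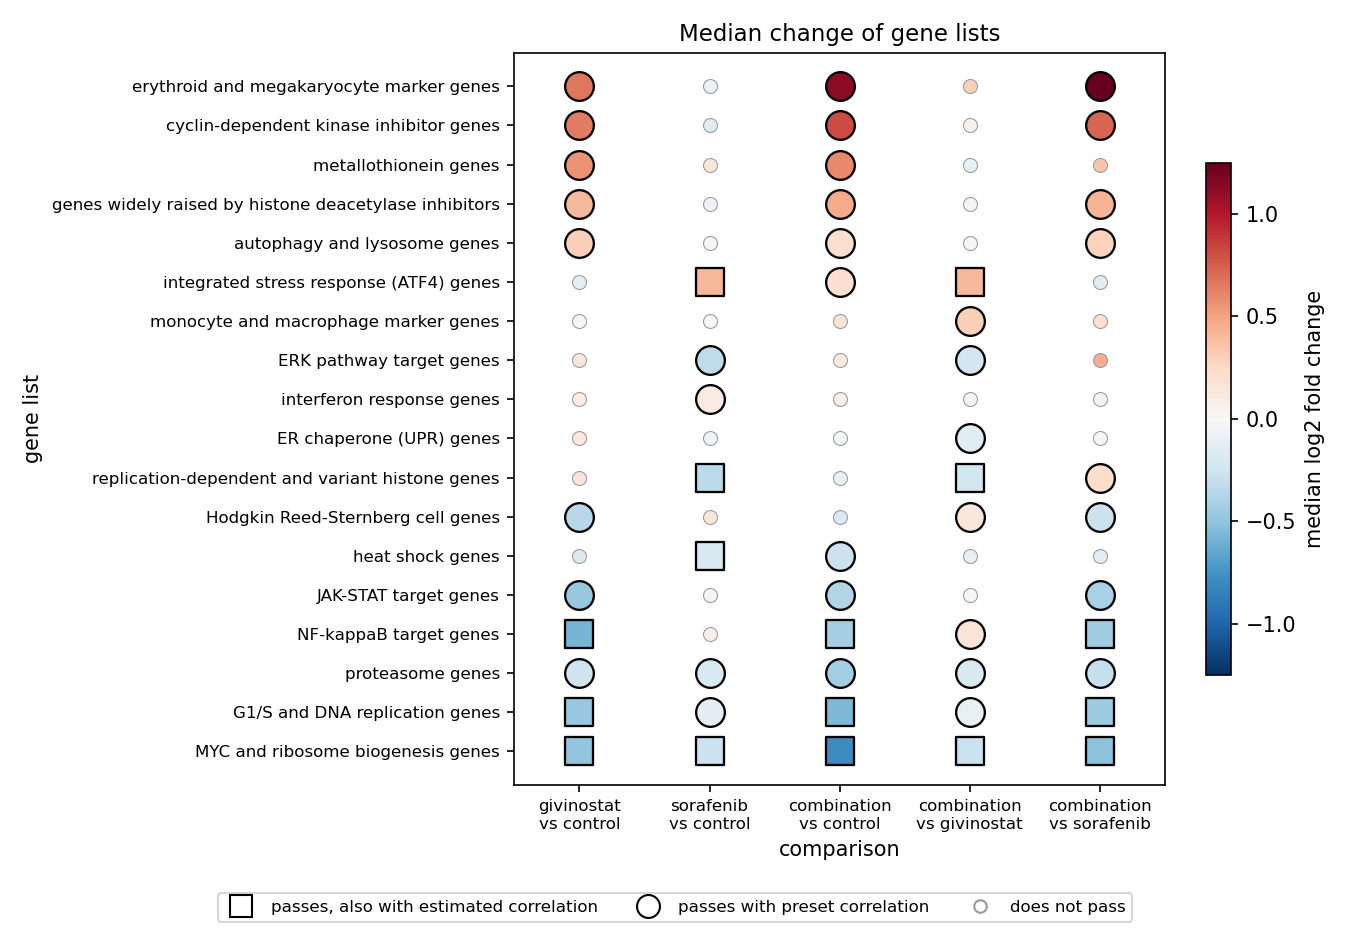
Median log2 change of the 18 gene lists called in at least 1 of the 5 comparisons (colour), with large symbols where the camera test passed and squares where it also passed with an estimated correlation. MYC and ribosome biogenesis genes were lower in each comparison, with medians from -0.80 to -0.27. The interferon median with sorafenib (0.12) turns to -0.05 under median scaling.

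The interaction asked whether both drugs together differed from the sum of each alone on the log2 scale. It passed for 2 of 10529 genes, with 1150 at an unadjusted p under 0.05. For GPR15 on chromosome 3 the interaction was -1.45 ± 0.17 (SE, n = 3 arrays per group, adjusted p = 0.0148): it was at least 3.20-fold higher with givinostat and not above background in control, sorafenib or combination, so a fall with sorafenib alone could not be measured and the background floor alone could give this value. For RRAD on chromosome 16, a RAS-related GTPase gene, the interaction was 0.92 ± 0.12 (adjusted p = 0.033), with falls of 1.73 with givinostat, 0.74 with sorafenib and 1.56 with the combination. EGR1 (-1.21 ± 0.28, adjusted p = 0.174) and FOS (-1.13 ± 0.38, adjusted p = 0.32) did not pass, so their lower values in the combination than with givinostat were not shown to differ from sorafenib's changes alone.

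GPR15's interaction was lost without control A, givinostat A, B or C, sorafenib C, or combination B or C (adjusted p from 0.0549 to 0.083). RRAD's was lost without any array but sorafenib B (adjusted p from 0.052 to 0.176), under median scaling (0.0824), with no detection filter (0.0994) and with the mean of its probes (0.159). Both calls were lost with the array letter as a block (0.094 for each). The count was 16 without background correction and 0 to 2 with an array left out. Of the 32 lists, the metallothionein list was called (0 of 8 members past, over all genes or adjusted over the list alone; median -0.25; adjusted p = 0.0254, but adjusted p = 0.338 with an estimated correlation), and this call was lost without control C (0.133), givinostat A (0.0797) or combination A (0.0545), under cyclic loess (0.0619) and with fry (0.0761). Median scaling put the median of all genes in this contrast at 0.19.

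Cell death genes moved both ways and their lists did not pass camera in any contrast. With givinostat, 3 of 15 BCL2 family genes rose and 2 fell (adjusted p = 0.965): the BH3-only gene BMF rose by 1.79 ± 0.15, BID fell by 1.09 ± 0.11 and the survival gene BCL2L1 fell by 0.65 ± 0.09. BCL2L11 was at 0.37 with givinostat (adjusted p = 0.199), -0.66 with sorafenib (adjusted p = 0.0996) and 0.27 with the combination (adjusted p = 0.335). It was at -0.10 in the combination against givinostat (adjusted p = 0.854), and its interaction was 0.56 (adjusted p = 0.526). PMAIP1, which encodes the BH3-only protein NOXA, was higher in the combination than with givinostat by 0.79 ± 0.12 (adjusted p = 0.00833, and 0.0539 without givinostat A). Of 17 death receptor and necroptosis genes, 2 rose and 3 fell with givinostat (adjusted p = 0.371), with TNFSF10, the TRAIL ligand gene, up by 1.01 ± 0.13 and the caspase inhibitor gene CFLAR at -0.76 ± 0.10.

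With sorafenib, CDKN1A (-0.23, adjusted p = 0.327) and TNFRSF8 (-0.38, adjusted p = 0.352) did not pass. The proliferation marker MKI67 was at 0.15 with givinostat, -0.08 with sorafenib and -0.09 with the combination (adjusted p = 0.577, 0.858 and 0.747). It was at -0.006 in the combination against sorafenib (adjusted p = 0.984). In the combination against givinostat, CDKN1A (-0.27), TNFRSF8 (-0.26) and MKI67 (-0.24) did not pass (adjusted p = 0.306, 0.591 and 0.572). Nor did these genes in the interaction (-0.04, 0.11 and -0.16, adjusted p = 0.957, 0.925 and 0.869). The G2/M and mitosis list was not called with givinostat, where 2 of 48 genes rose and 4 fell (adjusted p = 0.906), nor in any other contrast. Of 20 p53 targets, CDKN1A rose and 5 fell with givinostat (adjusted p = 0.574). Among 12 drug target genes, HDAC6 rose by 0.52 ± 0.09 with givinostat (adjusted p = 0.0011) and by 0.54 ± 0.09 with the combination. Against sorafenib, HDAC6 (0.34, lost without combination A, adjusted p = 0.0529) and HDAC3 (0.45) were higher in the combination. HDAC2 (0.34) and HDAC3 (0.28) passed with the combination against control, but HDAC2 was lost without control A or B or combination B or C (adjusted p up to 0.127). HDAC3 there was lost without control A or C or combination A or C (up to 0.103) and when only the compared groups were fitted (0.0513). Neither was called under median scaling (0.352 and 0.582) or with no detection filter (0.0704 and 0.061). HDAC1, HDAC4, HDAC5, HDAC8, HDAC9, HDAC10, ARAF and KIT did not pass in any contrast (smallest adjusted p = 0.0553, HDAC9 with givinostat). The drug target list was not called (adjusted p = 0.932 with givinostat, 0.584 with sorafenib and 0.908 with the combination). HDAC3 (0.32) and PDGFRA (-0.35) also passed with givinostat, but each call was lost without 4 of the 6 arrays: HDAC3 without control A or C or givinostat B or C (adjusted p up to 0.0706) and under median scaling (0.401), PDGFRA without control B or C or givinostat A or B (up to 0.0618).

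Metabolic lists did not pass camera in any contrast, though single members changed. Of 36 glycolysis and hypoxia response genes, 11 rose and 4 fell with givinostat (adjusted p = 0.117), with P4HA2 up by 1.26 and the glucose transporter gene SLC2A1 at -1.13. With the combination 15 rose and 8 fell (adjusted p = 0.232). Of 23 cholesterol synthesis genes, 5 rose and 4 fell with givinostat (adjusted p = 0.653), TM7SF2 by 1.08 and SREBF1 by 0.93 among the rises. Of 20 NRF2 targets, 3 rose and 2 fell (adjusted p = 0.996), and of 42 oxidative phosphorylation genes 2 rose and 6 fell (adjusted p = 0.822). The 41 cytosolic ribosomal protein genes, of which 2 rose and 0 fell with givinostat (adjusted p = 0.941), had a median of -0.01 with sorafenib (adjusted p = 0.752). That turned to 0.08 under median scaling (adjusted p = 6.30e-04) and 0.22 under cyclic loess (adjusted p = 0.00247). In the interaction their median of 0.01 turned to -0.14 under median scaling (adjusted p = 5.88e-06).

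The antigen presentation, B cell, T cell, and fibroblast and endothelial lists did not pass against control. With givinostat, 2 of 22 MHC class I and II genes rose and 6 fell (adjusted p = 0.599), with PSMB10 (-0.94) and TAP1 (-0.69) lower. Of 5 B cell markers, 1 rose and 1 fell (adjusted p = 0.965), and SPIB fell by 1.14. Of 5 T cell markers, 2 rose and 1 fell (adjusted p = 0.898), and of 6 fibroblast and endothelial markers 3 rose, COL1A1 (at least 2.09-fold) among them, and 1 fell (adjusted p = 0.307). These lists did not pass with sorafenib or the combination.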

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

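Of the tests here, the 1 on background correction and normalization was chosen after the result was seen, and the rule for reading the KRTAP9 test was also changed after its value was seen. The other tests were written before their values. The interaction of the 2 drugs stood out for 2 genes because a test of the difference between sorafenib's effects without and with givinostat passed. It was -1.45 for GPR15 and 0.92 for RRAD on the log2 scale. GPR15 was at background in control, sorafenib and combination, so the floor alone could give its value, and neither call held with the array letter as a block (adjusted p = 0.094 for each). Over 100 regroupings of the 12 arrays into 4 groups of 3, drawn at random with the real one included, 2 gave at least as many interaction genes as the labels (real 2, highest other 608). The regrouping with 608 kept the 3 combination arrays together and mixed arrays with and without givinostat in other groups. Such mixing puts the effects of each drug into the interaction or into the spread within groups, so these regroupings cannot judge the 2 interaction genes. For the count of genes that differed among the 4 groups, 1 of 100 regroupings, the real one, did as well (real 4902, highest other 2). That argues against a chance assignment of single arrays to groups. Differences between cultures are not covered, since the labels do not say whether arrays came from separate cultures.

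Splits of 3 against 3 arrays number 10 per comparison, too few for a share under 0.05. As many genes passed in 1 of 10 splits, the real one, for givinostat (real 3509, highest other 0), sorafenib (real 482, highest other 1) and the combination (real 4356, highest other 0) against control. The same held for the combination against givinostat (real 141, highest other 0) and against sorafenib (real 3720, highest other 0).

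Sorafenib array C lay apart from sorafenib arrays A and B. If it had responded more to sorafenib, its distance from A and B would have followed the genes that sorafenib changed on top of givinostat. The slope was 0.0478 (-0.0101 to 0.0988 over resampled genes), where A and B against control had 0.612. Arrays A and B, each against the other 2, had slopes of -0.038 and -0.010. Over these 141 genes this argues against a larger response, though the upper bound was just under the limit set beforehand. The interval resamples genes, so it leaves out the spread between arrays. On the second principal component, which separated arrays with sorafenib, C lay furthest out (-21.9, A -6.4, B -9.8), and this was not weighed in the test. If dim probes in a dimmer array had set array C apart, the brightest of 3 equal classes of genes would have been spared. Their deviation was 1.499 times that of A and B (1.47 to 1.52), against 1.19 in the dimmest class, which argues against that explanation. The labels give no group that sets array C apart, so no biological explanation beyond the size of the response was tested, and the cause is not known.

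More genes were at least 2-fold higher than lower with givinostat (341 against 115). If a floor hid the falls of dim genes, the excess would be missing among the brightest of 3 equal classes of genes. There 61.7% were higher (29 against 18; exact interval 46.4 to 75.5%), against 76.1% in the dimmest class, so this test could not decide. Over 4 other backgrounds and scalings the lowest share was 62.4%, under median scaling, which argues against the processing as the whole cause. That more open chromatin under a histone deacetylase inhibitor raises more genes than it lowers is a hypothesis that these data may fit but do not test.

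The fall of 3 KRTAP9 genes with sorafenib could come from 1 transcript read by several probes, which would make their deviations from the group means rise and fall together. Their mean correlation was 0.0147 (lowest -0.29), under the bound of 0.2 that had been set beforehand as arguing against this explanation. After that value was seen, the bound was judged unable to decide, and the test was read as undecided. The reasons were the spread of 1000 random sets of 3 genes of like brightness (95th percentile 0.389) and that deviations of probes near background can be measurement noise alone. A response of each gene of its own remains a hypothesis that was not tested.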

How the results depend on the processing

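The tests of the relation and the lists without single arrays, and those without sorafenib C where its group was not compared, were chosen after the result was seen. Gene calls were rerun for the largest changes, the genes always reported, and the smallest-p members of called lists and some other lists. These include genes not named above and leave out some that are, such as EGR1, FOS, P4HA2 and SLC2A1 with givinostat. The planned settings numbered 11, or fewer for genes not detected on all 12 arrays. Over these, the calls of 79 of 84 such genes with givinostat and 86 of 91 with the combination kept direction and side of the threshold. So did 71 of 76 for combination against sorafenib, 19 of 44 with sorafenib and 17 of 28 for combination against givinostat. Neither interaction call did. With each array of the compared groups left out, and sorafenib C also where its group was not compared, 76, 88, 73, 23 and 13 of these did, and neither interaction call. For genes changed with sorafenib (482) the count was 214 with no detection filter, 744 with a trended robust prior, 75 with only the compared groups and 166 to 403 with an array left out (without control A 221, control B 245, control C 170, sorafenib B 166, sorafenib C 251). For combination against givinostat (141) it was 319 without background correction and 319 with the authors' values, 88 under median scaling, 68 with no detection filter, 347 with a trended prior, 358 with array weights (sorafenib C had a weight of 0.351), 83 with only the compared groups, and 32 to 224 with an array left out (givinostat A 32, B 71, C 52; combination A 59, B 39, C 46; sorafenib C 224). For the interaction (2) it was 16 without background correction and 16 with the authors' values, 1 each under median scaling, no detection filter, detection on all 12 arrays and the mean of probes, 19 with a trended prior, 0 with the array letter as a block and 0 to 2 with an array left out. The labels do not say that letters pair arrays, and the deviations leave it open: 5 of 18 same-letter and 2 of 36 different-letter pairs correlated at over 0.1, and 6 of 12 arrays correlated best with their own letter. Genes at least 2-fold changed without background correction, with the authors' values and when detected on all 12 arrays were 135, 136 and 219 for givinostat (456), 3, 3 and 10 for sorafenib (28), 205, 206 and 337 for the combination (636), 4, 4 and 5 against givinostat (15), 124, 126 and 213 against sorafenib (466), and 0, 0 and 0 for the interaction (1). The last was 3 with a trended prior, 0 with the block and 0 to 2 with an array left out. Lower counts follow from background left in, which shrinks log2 changes, and from fewer genes tested. The correlation of givinostat and sorafenib changes (0.289) was 0.338 under median scaling, 0.321 under cyclic loess and 0.252 to 0.345 with an array left out. Reversed in direction were NDUFB4 with sorafenib without control B (0.0739; -1.2 without control A), the ribosomal protein list with sorafenib under median scaling (adjusted p = 6.30e-04) and cyclic loess (0.00247) and in the interaction under median scaling (5.88e-06), and the ERK list between combination and givinostat on genes detected on all 12 arrays (0.783). The detection filter and the choice of probe were redone with each array left out, so another NDUFB4 probe may stand behind its turn. Detection on all 12 arrays left out EGR1 and FOS, so the ERK list that turned lacked both of its called falls. For all other changes the cause was not tested. With arrays, signal over background limits the folds of genes near background, and the number of arrays limits precision.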
